A study of Mus musculus with 6 samples.

How the data were processed

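Poly(A) tails were profiled by mTAIL-seq, which ligates an adaptor to the 3' end of RNA and reads the end of each transcript together with its tail, in sorted naive CD4 T cells of mice. Each of 6 libraries had its own files, with 3 libraries from littermate control mice with floxed Btg1 and Btg2 alleles (WT) and 3 from mice that also carried CD4-Cre and so lacked both genes in T cells (DKO). The series text gives 3 replicates per genotype, whereas the growth protocol speaks of 2 pairs of mice, and which libraries share mice is not given in the sources used here. The p-values therefore measure the spread between libraries, part of which may be technical.

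The authors deposited, per library, a table of all tags, a table of the mapped tags, a table linking tags to gene IDs and a table per gene ID. A tag is a group of reads, and the number of reads in it is a whole-number count in the deposited tables. The submitters' processing notes name GSNAP, bedtools and the mouse builds mm10 and GRCm38. The tail caller, the annotation release and the meaning of the flag column are not given in the sources used here. Per the file headers, the gene tables hold a mean and a median tail length in nt and tag counts per gene ID in classes of tail length. Recomputation from the mapped tags gave the deposited tag counts for 99.96% to 100% of gene IDs, and showed that the deposited mean is a geometric mean over tags with a tail of at least 5 nt (within 1e-06 nt). Tags with no tail are listed at 0 nt, and no length above 231 nt is listed.

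The tail length after mapping was used. A tag counted as tailed at 5 nt or more, as in the deposited gene tables. Library values were computed over tailed tags linked to at least 1 gene ID, each counted once. Values per gene ID counted a tag under each ID it was linked to, as the authors did. Between 1.63% and 7.15% of linked tags had more than 1 ID. Between 19.0% and 28.3% of mapped tags were linked to a gene ID in the files used here, so the unlinked tags enter only as an alternative. An added base was counted when it occurred in the string of non-templated bases listed for the tag.

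The gene IDs are Ensembl IDs with versions. Of 6469 IDs with tailed tags, 0 matched a symbol, because 0 of the 49997 rows of the reference gene table (assembly GRCm38.p6) carry an Ensembl ID. The gene lists fixed before the data were examined, the check of Btg1 and Btg2, and the separation of nuclear from mitochondrial transcripts are therefore not analysed here. All tailed, gene-linked tags were used where the plan named nuclear mRNA. Because the files do not pair IDs with names, at most 2 IDs higher and 2 lower in DKO are printed in all. The rule fixed before the data were examined names, per test, up to 8 IDs in each direction past an adjusted p of 0.05 with no overlap between genotypes, and the 8 with the smallest p as values if fewer than 5 pass. Fewer than 5 passed in both tests, and the printed IDs come from the 8 with the smallest p, except 1 that is marked as chosen after its values were seen.

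Depth ranged from 3943 to 24024 tailed, gene-linked tags per library. The 95% exact (Clopper-Pearson) intervals given for shares cover counting error only, and tags from PCR-amplified libraries may not be independent molecules. Single values per library were compared with two-sided exact permutation tests of 3 against 3 libraries, which cannot give a p below 0.1. Of these, 13 comparisons of tail length, tail classes and added bases over gene-linked tags were adjusted together by Benjamini-Hochberg, and none had an adjusted p below 0.65. The exact p-values of alternatives and of the closing observations are outside that family and are unadjusted. The log2 mean tail length per gene ID was tested with limma 3.58.1 (lmFit and eBayes) over the 44 IDs with at least 10 tailed tags in every library. Tag counts were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood) over 170 IDs. Both used Benjamini-Hochberg adjustment and a threshold of 0.05. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1 were used.

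Both tests were run on simulated data with known answers. For tail length, 15 of 44 IDs were changed, all towards longer tails in DKO. Of these, 0.3% of 1.2-fold and 89.7% of 1.5-fold changes were recovered, and 29% of 1.2-fold changes with the library group as a block. For tag counts, 42 of 170 IDs were changed, in both directions, and 33.3% of 2-fold and 85.7% of 4-fold changes were recovered. The simulated counts had the same dispersion for every ID and no difference in composition between libraries of a genotype. The simulated tail lengths varied by tag sampling and a library-wide shift, with no further spread of single IDs between libraries. Recovery in the real libraries may therefore be lower, as it may where a smaller share of IDs changed.

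The libraries numbered 3 of both genotypes stood apart from those numbered 1 and 2. In them 29.6% and 31.7% of mapped tags had no tail, against 6.69% to 8.24% in the other 4. Chi-square per degree of freedom between tag counts of WT libraries was 1.85 for numbers 1 and 2 and 8.68 to 11.0 for pairs with number 3. In DKO it was 1.64 against 2.68 to 3.19. No pair of replicates was within sampling noise. Comparisons are therefore also given within numbers 1 and 2 and within number 3, a choice made after seeing the data. Deviations from the genotype means were also compared between same-numbered libraries, whose correlations over the tested IDs were 0.25, 0.40 and 0.52 for tail length and 0.14, 0.21 and 0.38 for tag count. As each exceeded 0.1, the numbers were treated as pairing the libraries. Libraries of different number among 1 and 2 (WT replicate 2 with DKO replicate 1, and WT replicate 1 with DKO replicate 2) also correlated. Their values were 0.11 and 0.33 for tail length, and 0.38 and 0.29 for tag count. For tag count both exceeded the same-numbered values of numbers 1 and 2, so the tag counts do not tell these numbers apart. For tail length, 0.33 exceeded the 0.25 of WT replicate 1 with DKO replicate 1. Number 3 stood apart in both genotypes and enters each genotype mean. Numbers 1 and 2 therefore deviate together under either pairing, and the correlations do not establish how they pair. On wider sets of IDs, the lowest correlations were 0.074 and 0.061, and the labels do not say that a number marks a shared day or litter. Alternatives comprised other averages, filters, weights, scalings and tools, a replicate block, and each library left out in turn.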

Results

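mTAIL-seq libraries of naive CD4 T cells (TCRβ+ CD4+ CD25− CD62L-high CD44-low) were compared between WT mice and mice lacking BTG1 and BTG2 in T cells, with 3 libraries per genotype. BTG1 and BTG2 are antiproliferative proteins that bind the CCR4-NOT deadenylase, the complex that shortens poly(A) tails, and the series concerns their part in mRNA destabilization. The WT libraries held 96000, 62902 and 37609 mapped tags, of which 16953, 11386 and 7177 had a tail and were linked to a gene ID. The DKO libraries held 97097, 90156 and 22311 mapped tags, of which 20674, 24024 and 3943 were tailed and linked. The libraries numbered 3 were the smallest of both genotypes, and about 30% of their mapped tags had no tail.

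The first comparison asked whether poly(A) tails were longer without BTG1 and BTG2. Mean tail length was 64.4 nt ± 14.1 (SD, n = 3) in WT and 70.7 nt ± 9.10 (SD, n = 3) in DKO cells. The difference of 6.26 nt was smaller than the spread between libraries (exact permutation test, two-sided p = 0.6). WT replicates 1 and 2 had means of 74.7 and 70.3 nt, and DKO replicates 1 and 2 had 72.3 and 78.9 nt. Replicate 3 had 48.3 nt in WT and 60.9 nt in DKO. The difference was 3.09 nt within numbers 1 and 2, where the genotypes overlapped, and 12.6 nt within number 3, which has 1 library per genotype. Counting error was small beside these gaps, with standard errors over tags between 0.261 and 0.556 nt. Without WT replicate 3 the difference turned (DKO minus WT, -1.8 nt), a comparison that leaves DKO replicate 3 with no WT library of its kind.

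The median over tags was 64, 61 and 45 nt in WT and 66, 69 and 56 nt in DKO, so that it was higher in DKO within each number, by 2, 8 and 11 nt. A sign-flip test over 3 such pairs cannot give an exact p below 0.25, which is the value it gave.

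**Figure D1:**
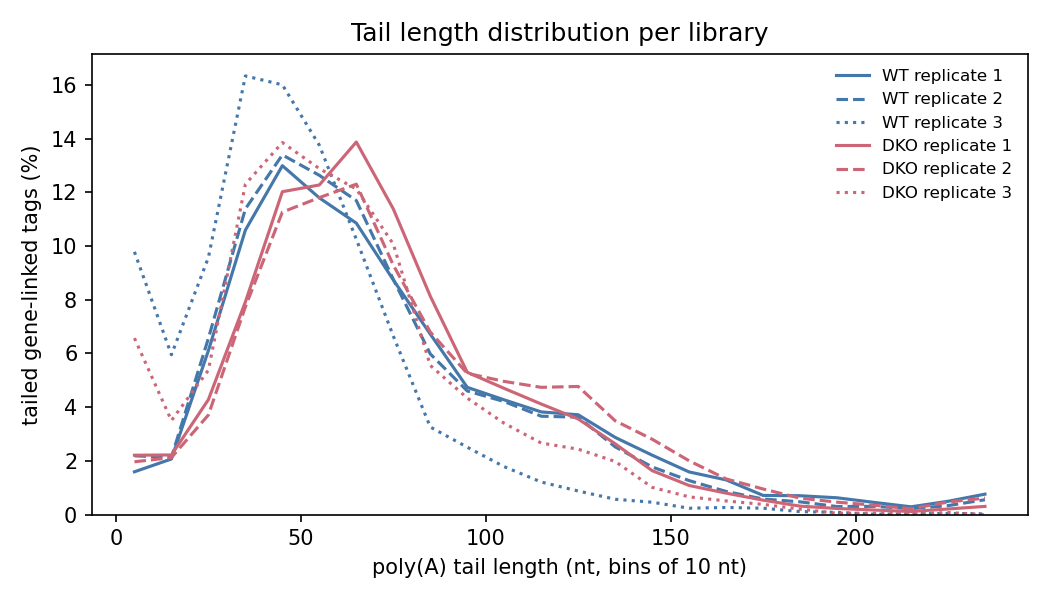
Share of tailed, gene-linked tags (y axis, percent) by poly(A) tail length (x axis, nt, in bins of 10 nt, the first holding 5 to 9 nt) for each of the 6 libraries, with genotype by colour and replicate by line style. In replicates 1 and 2 the fullest bin was 40 to 49 nt in WT and 60 to 69 nt in DKO, and both libraries numbered 3 were shifted to shorter tails.

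Of 5 classes of tail length, that of 60 to 89 nt was the one in which the genotypes did not overlap. These tails made up 26.3%, 26.4% and 20.2% of tags in WT and 33.4%, 28.4% and 27.7% in DKO. Every DKO library exceeded every WT library, with a mean difference of 5.54 percentage points (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give, and 0.65 after adjustment over 13 comparisons). Tails of 30 to 59 nt went the other way, at 39.6% ± 5.69 (SD, n = 3) in WT and 34.0% ± 4.40 (SD, n = 3) in DKO (exact permutation p = 0.3), and were lower in DKO in 3 of 3 same-numbered pairs. Tails of at least 90 and under 150 nt made up 16.5% ± 7.88 (SD, n = 3) in WT and 21.3% ± 5.13 (SD, n = 3) in DKO (exact permutation p = 0.5), and were higher in DKO in 3 of 3 pairs, by 0.311, 5.63 and 8.41 percentage points. For both classes the sign-flip test over pairs gave its smallest exact p, 0.25. The longest class, 150 nt and above, held 4.29% ± 2.98 (SD, n = 3) in WT and 4.24% ± 2.56 (SD, n = 3) in DKO, and its order differed between numbers.

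Short tails, under 30 nt and thus about the span of a single poly(A)-binding protein, made up 15.3% ± 8.67 (SD, n = 3) of tags in WT and 10.7% ± 4.18 (SD, n = 3) in DKO (exact permutation p = 0.5). Within numbers 1 and 2, the WT shares were 9.77% (95% exact interval 9.33 to 10.2) and 10.9% (10.3 to 11.5), and the DKO shares were 8.71% (8.33 to 9.10) and 7.80% (7.46 to 8.14). Within number 3 the shares were 25.3% (24.3 to 26.3) in WT and 15.4% (14.3 to 16.6) in DKO. The share was thus lower in DKO in each library group, with differences (DKO minus WT) of -2.07 and -9.86 percentage points. A permutation within library groups gave an exact p of 0.17, the smallest it allows. Gene IDs of median tail under 20 nt took 12.7% of tailed tags in WT replicate 3 and 8.17% in DKO replicate 3, and 2.22% to 3.33% in the other libraries. Without these IDs, a choice made after seeing the data, the shares under 30 nt were 8.09%, 8.62% and 15.4% in WT and 5.99%, 5.23% and 8.38% in DKO (exact permutation p = 0.2). Under 20 nt the order within numbers 1 and 2 was lost, with 3.66% and 4.32% in WT and 4.43% and 4.09% in DKO. Without the same IDs these shares were 2.04% and 2.10% in WT and 1.89% and 1.64% in DKO (exact permutation p = 0.5 over all 6 libraries). Those IDs were picked by their tail length in these same libraries. Leaving them out therefore acts on the measure itself and does not show that the order is restored. Without WT replicate 3 the DKO share under 30 nt was 0.326 percentage points higher, again with DKO replicate 3 left unmatched.

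**Figure D2:**
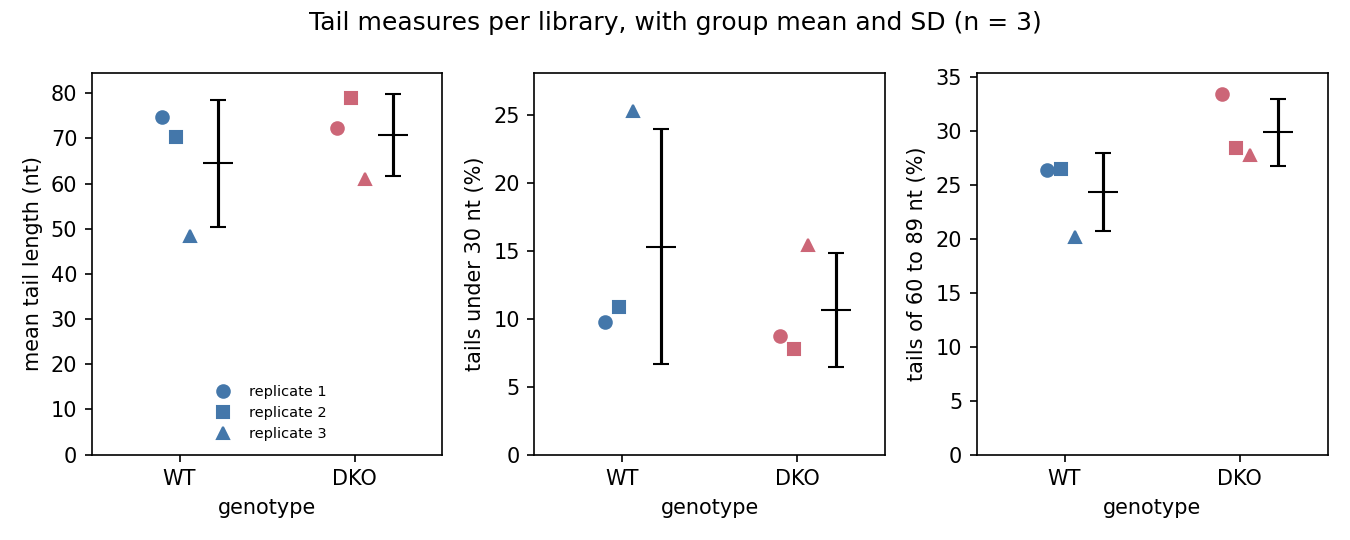
Mean tail length (nt), share of tails under 30 nt (percent) and share of tails of 60 to 89 nt (percent) for each library (points, shape by replicate number, colour by genotype), with the group mean and SD over 3 libraries in black. All 3 DKO libraries lie above all 3 WT libraries for tails of 60 to 89 nt, while the genotypes overlap in the other 2 measures, in which both libraries numbered 3 lie apart from the rest.

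The second comparison held the set of transcripts fixed, over the 44 gene IDs with at least 10 tailed tags in every library. The median of their mean tail lengths was 67.0 nt ± 11.2 (SD, n = 3) in WT and 74.2 nt ± 7.54 (SD, n = 3) in DKO (exact permutation p = 0.5). Of the 44 IDs, 41 had a higher group mean in DKO, with a median log2 change of 0.10. Within numbers 1 and 2, 28 of 44 were higher (median log2 change 0.04), and within number 3, 39 of 44 were (median log2 change 0.26). Without WT replicate 3, 17 of 44 were higher (median log2 change -0.03).

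No single ID passed the threshold. In limma, 0 of 44 IDs had an adjusted p under 0.05, 2 had an unadjusted p under 0.05, and the smallest adjusted p was 0.82. In 3 IDs all DKO values lay above all WT values and in 0 below, where chance gives 4.4 of 44 (10%). The 8 IDs with the smallest p all had longer means in DKO. The smallest p belonged to ENSMUSG00000000682.7, at 56.0 nt ± 8.60 (SD, n = 3) in WT and 74.7 nt ± 6.66 (SD, n = 3) in DKO (log2 fold 0.42, SE 0.16, limma adjusted p = 0.82).

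The third comparison concerned bases added to the 3' end. A U was present on 2.85% ± 0.660 (SD, n = 3) of tailed tags in WT and 2.48% ± 0.232 (SD, n = 3) in DKO (exact permutation p = 0.5). It was lower in DKO in 3 of 3 same-numbered pairs (DKO minus WT, -0.119, -0.126 and -0.870 percentage points), with a sign-flip exact p of 0.25 and a p of 0.17 by permutation within library groups, each the smallest possible. Over all mapped tags the shares were 2.39% ± 0.293 (SD, n = 3) in WT and 2.34% ± 0.272 (SD, n = 3) in DKO (exact permutation p = 0.8). Uridine was more frequent on short than on longer tails in each library. Among tails under 30 nt it was on 9.56% ± 0.560 (SD, n = 3) in WT and 9.22% ± 0.130 (SD, n = 3) in DKO, and among longer tails on 1.66% ± 0.0668 and 1.67% ± 0.120 (SD, n = 3). By number, DKO minus WT was -1.10, -0.0986 and 0.164 percentage points in short tails and 0.0737, 0.129 and -0.186 in longer ones. The order of the overall U share in the 3 pairs was thus not kept within either class. The overall U share also depends on the share of short tails, which was lower in DKO within each number. It is therefore not separate from that difference, whose part in it was not computed. The share was 14.5% and 12.4% in tails of 5 to 9 nt, and 0.805% and 0.878% in tails of 90 nt and above, for WT and DKO respectively. Only in tails of 30 to 59 nt did all DKO libraries lie on one side of all WT libraries, at 2.20% ± 0.0894 (SD, n = 3) in WT and 2.52% ± 0.177 (SD, n = 3) in DKO, a class picked out after all 6 were seen. The exact permutation p for the genotype difference was 0.4 in short and 1.0 in longer tails.

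**Figure D3:**
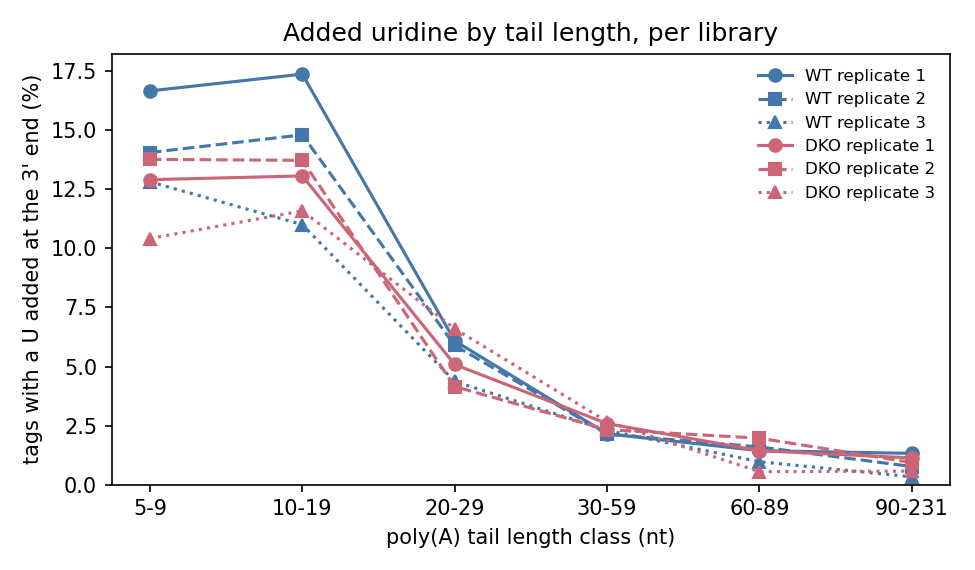
Share of tailed, gene-linked tags with a U added at the 3' end (y axis, percent) by tail length class (x axis, nt) for each of the 6 libraries, with genotype by colour and replicate by marker and line style. In each library the share was above 10% in tails of 5 to 19 nt and below 3% from 30 nt upwards, and the genotypes overlapped in every class except 30 to 59 nt.

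A G was present on 0.324%, 0.316% and 0.348% of tags in WT and on 0.435%, 0.366% and 0.406% in DKO. All DKO values lay above all WT values (exact permutation p = 0.1, the smallest possible, and 0.65 after adjustment), although the 95% exact intervals of single libraries overlapped, such as 0.244 to 0.422% in WT replicate 1 and 0.350 to 0.535% in DKO replicate 1. Over all mapped tags the G shares overlapped, at 0.497%, 0.367% and 0.546% in WT and 0.484%, 0.431% and 0.658% in DKO. A C was present on 0.267% ± 0.0448 (SD, n = 3) in WT and 0.318% ± 0.127 (SD, n = 3) in DKO (exact permutation p = 0.7).

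The fourth comparison asked which gene IDs differed in tag count. In edgeR's quasi-likelihood test, 0 of 170 IDs had an adjusted p under 0.05, with 13 at an unadjusted p under 0.05. DESeq2 also gave 0, with 8 unadjusted. The median log2 change over the 170 IDs was -0.05 with TMM (78 higher in DKO, 92 lower) and 0.24 with library totals alone (117 higher, 53 lower), so that log2 values per ID are relative to the scaling. With the replicate number as a block, edgeR called 3 IDs, 1 higher and 2 lower in DKO, each at an adjusted p of 0.018. The 2 lower ones also had the smallest p without the block. ENSMUSG00000060019.5 had 32, 19 and 6 tags in WT and 13, 8 and 1 in DKO, a log2 fold of -1.82 (SE 0.52, edgeR adjusted p = 0.32) without and -1.95 (SE 0.51) with the block. ENSMUSG00000062083.1 had 47, 42 and 10 tags in WT and 18, 20 and 4 in DKO, a log2 fold of -1.64 (SE 0.49, edgeR adjusted p = 0.32) without and -1.71 (SE 0.46) with the block. The ID higher in DKO was ENSMUSG00000025508.13, with 3, 3 and 10 tags in WT and 23, 21 and 16 in DKO, and a log2 fold of 1.86 (SE 0.51) in the blocked fit. It was chosen after its values were seen.

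Without both libraries numbered 3, edgeR called 30 of 241 IDs, 7 higher and 23 lower in DKO, and without WT replicate 3 alone it called 8 of 241, 1 higher and 7 lower. Of the 30, 16 had the same direction in number 3 (with a pseudocount of 0.5), which is close to an even split. Number 3 thus gave no support for these calls as a set, but it could hardly test them. It has 1 library per genotype, with 7177 (WT) and 3943 (DKO) tailed, gene-linked tags, so counts per ID were low. The same share over all 241 tested IDs is not given here, so the split does not count against the calls either.

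The last comparison asked whether gene IDs with longer tails in DKO also had more tags there. Across the 44 IDs the log2 changes in tail length and tag count had a Spearman rho of 0.17 (permutation p = 0.26) and a Pearson r of 0.18 (permutation p = 0.25). These are correlations across genes, which are not independent replicates.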

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

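No comparison of tail length passed a threshold under any setting run. For values per library this could not have been otherwise, since exact tests of 3 against 3 libraries cannot give a p below 0.1. With fewer libraries or with pairs the smallest possible p is no lower. Their failure to pass therefore says nothing about stability, and for these values only the size of the differences is compared below. The limma tests per gene ID could have passed. Leaving out each library in turn gave differences (DKO minus WT) of -1.8 to 11.4 nt in mean tail length, 0.743 to 10.8 nt in the median over gene IDs, -7.44 to 0.326 percentage points in tails under 30 nt and -0.584 to 0.0086 percentage points in tags with a U. The ends at -1.8 nt, 0.326 and 0.0086 came from leaving out WT replicate 3, which by construction leaves DKO replicate 3 without a WT library of its kind. The count of IDs with a changed tail length stayed at 0 in every alternative, the replicate block included, where the smallest limma adjusted p was 0.15 (0.15 to 0.98 over the alternatives). The count of IDs with a changed tag count was 0 to 8 when 1 library was left out (8 without WT replicate 3, and 0 without any other single library). It was 3 with the replicate block, 3 with the library group as a block and 30 with numbers 1 and 2 only, the latter 2 chosen after seeing the data; the cause was not tested. The replicate block changed no other call. The correlation across genes was 0.0075 to 0.29 when 1 library was left out and -0.10 over the 12 IDs with at least 30 tags in every library, where fewer IDs were tested. The difference in tags with a C was -0.018 to 0.106 percentage points when 1 library was left out (-0.018 without DKO replicate 3), -0.033 over all mapped tags and -0.033 in numbers 1 and 2. It was 0.532 in tails under 30 nt (exact permutation p = 0.2), where the difference in tags with a G was 0.373 (exact permutation p = 0.1, the smallest possible). These short tails with a C numbered 6 to 18 per library in WT and 11 to 20 in DKO, and those with a G 12 to 15 and 10 to 20. Over all mapped tags the G shares of short tails overlapped, at 1.13% to 2.11% in WT and 1.73% to 2.74% in DKO. Centring each library on its median, which removes a shift common to all IDs, turned 41 of 44 IDs higher in DKO into 11 of 44. After centring, higher or lower is relative to the library median, so this does not bear on the direction of the shift itself. The gene list and Btg1 and Btg2 alternatives were not run, for want of gene names. Depth limits the test of tail length per gene ID to 44 of 6469 IDs, and 1.2-fold changes in tail length were mostly not recoverable at this size.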

Other observations

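Of the tests below, those that left out the 10 most-tagged gene IDs or used tags with a single ID had their predictions written down first, as had the counts over the 10 splits of 3 against 3 libraries, and the others, including the splits with a replicate block and among numbers 1 and 2, were chosen after the values were seen.

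DKO libraries held tags from more gene IDs than WT libraries at the same depth. Each tailed tag was counted once for every gene ID it was linked to. Among 3990 such links drawn without replacement from each library, which is all of those in DKO replicate 3, the expected number of distinct IDs was 1145 ± 19.1 (SD, n = 3) in WT and 1392 ± 6.82 (SD, n = 3) in DKO, a ratio of 1.21. The lowest DKO library exceeded the highest WT library by 221 IDs (exact permutation p = 0.1, unadjusted and the smallest possible). The 10 most-tagged IDs took 39.2%, 37.3% and 36.7% of links in WT and 27.1%, 27.6% and 30.1% in DKO.

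The excess of gene IDs in DKO was weighed against technical explanations. A few IDs taking a larger share of the links in WT may account for part of it, since without the 10 most-tagged IDs the ratio was 1.10 among 2789 links, but the lowest DKO library still exceeded the highest WT library by 94.5 IDs at that smaller depth. With tags of a single ID, drawn at 3897 tags, the gap was 222 IDs, which argues against tags counted under several IDs. The difference between the library groups is not the source either, because the excess was at least 240.1 IDs both within numbers 1 and 2 and within number 3. The genotype and a difference in how the libraries of each genotype were made stay open, and neither was tested.

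A second pattern was the lower share of tails under 30 nt in DKO. It is not produced by the library groups alone, since the difference was -2.07 percentage points within numbers 1 and 2, where both DKO shares lay below both WT shares. Within the 44 common IDs a different mix does not produce it, since with these weighted equally the difference was -4.39 percentage points. The shares were 10.4%, 9.05% and 16.4% in WT and 7.61%, 6.62% and 8.48% in DKO (exact permutation p = 0.1, unadjusted and the smallest possible). With these weights the difference was -2.62 percentage points within numbers 1 and 2, -7.93 within number 3 and -2.16 without WT replicate 3. A related measure was the share under 30 nt among tails under 60 nt. With the 44 IDs weighted equally it was 19.8%, 15.2% and 24.5% in WT and 13.6% in each DKO library (exact permutation p = 0.1, unadjusted and the smallest possible). With the links of the 44 IDs pooled, it was higher in DKO replicates 1 and 2 (22.4% and 20.85%) than in WT (19.6% and 19.8%), but lower in number 3 (29.8% against 37.8%). For this measure the order within numbers 1 and 2 thus depended on the weighting of IDs. The genotype stays open, as do the pairs of mice behind the libraries and the mix of the other gene IDs, and none of these was tested.

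A further pattern was the shorter tails of the libraries numbered 3 in both genotypes. Over the same 44 IDs the median log2 ratio of number 3 to numbers 1 and 2 was -0.41 in WT and -0.186 in DKO, with 43 and 38 IDs shorter, so a different mix of IDs is not the whole source. Nor is loss of the longest tails alone the whole source, since over all gene-linked tags the share under 30 nt among tails under 60 nt was 35.4% in number 3 against 21.6% and 22.5% in WT, and 28.4% against 21.3% and 20.2% in DKO, a smallest excess of 7.06 percentage points over the higher of numbers 1 and 2. The excess in DKO was 1.18 percentage points without IDs of median tail under 20 nt, where DKO replicates 1 and 2 differed by 1.12. With the 44 IDs weighted equally it was -0.0112. For single IDs in DKO that loss therefore stays open, as does that loss together with a different mix of IDs. No biological explanation was tested, since the design gives none.

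The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. For tail length the real split gave 0 IDs and the highest other split 1. For tag count the real split gave 0 and the highest other 7, a split that sets WT replicate 2 and DKO replicates 1 and 2 against the rest and so keeps both libraries numbered 3 on one side, which points to a structure of the libraries. With the replicate block, the real split gave 3 tag count calls and the 3 other splits that part every pair gave 0 each. For tail length with the block, the real split gave 0 calls and 1 of the other splits gave 1. Among the 4 libraries numbered 1 and 2, the real split gave 30 tag count calls and both others 0. These splits are fewer still, so they cannot give a share under 0.05 either. As it is not given which libraries share mice, they do not set the genotype apart from mouse or technical differences.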
